A study of Mus musculus with 31 samples.

How the data were processed

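Arrays were hybridised with labelled RNA from 31 pairs of mouse gonads at embryonic day 14.5. Per the labels' protocols, each pair of gonads was 1 biological replicate, 40 ng of total RNA was amplified because concentrations varied, and the product was labelled with biotin. The deposited values are linear signal intensity per probe set, made by the authors with MAS5 per the submitters' processing notes, whose version and settings are not given in the sources used here. The values show the form of MAS5 global scaling: the trimmed mean of every array is 500.0, there is no log scale and no centring, and values run from 0.0216 to 47341. Median signal per array ran from 120.6 to 168.8. Amplification of small RNA amounts can favour transcript ends, and the 3' to 5' ratio of actin control probe sets ran from 0.958 to 1.212 and that of Gapdh from 2.343 to 3.216. Arrays have no read depth, so the number of arrays sets the precision.

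The arrays hold 45101 probe sets, 64 of them controls, which were left out. By the platform annotation, 34945 probe sets have 1 gene symbol, 932 several and 9160 none, and none was named from a probe set with several. Symbols were looked up by Entrez identifier in a RefSeq table, which matched 34741 probe sets and changed 0 symbols, and 204 kept the platform's name. Of 18193 genes named, 9010 have several probe sets, and the probe set with the highest mean over all arrays stood for the gene. Values were taken as log2(signal + 16), which understates fold changes of genes with low signal, so fold changes are on that scale. Genes above their own array's median of all probe sets on at least 3 arrays were kept, leaving 11777. All columns of the value table were used.

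Groups came from the sample titles and genotypes. All 31 arrays entered 1 limma fit (version 3.58.1 in R 4.3.3) of 8 group means, with contrasts, eBayes with a trend, 23 residual degrees of freedom and a median prior of 6.68. Adjusted p-values are Benjamini-Hochberg values over the genes of 1 comparison, and a gene was called at an adjusted p under 0.05. Errors of fold changes are SE from limma, and SD is between arrays of a group. The SE of a median over genes is from the spread between those genes, taken as independent, and measures no error between arrays. The comparisons, tests, gene lists, rule for named genes and alternative settings were fixed before the data were examined. The interactions of sex with Ctnnb1 loss and of sex with Sox9 loss, and the genes whose group signals are given, were chosen after the values were seen. Tests of explanations for single patterns were set up after the data were examined, and those chosen after their own result was seen are named with them.

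Named genes were, per comparison, Sox9, Ctnnb1 and sex chromosome genes, up to 4 members of each list by adjusted p with others needed to say which did not move, and the 8 largest rises and falls among called genes with arrays that do not overlap between the groups and a mean above the median of the higher group, without predicted genes. The lists were Sertoli cell and testis, pregranulosa and ovary, canonical WNT target, fetal Leydig and steroid synthesis, adrenal cortex, interstitial and hedgehog target, peritubular myoid and smooth muscle, pan-germ cell, meiosis, fetal male germ cell, endothelial, macrophage and leukocyte, erythroid, mesonephric duct and tubule, proliferation, and immediate early and heat shock genes. Each was tested against the other genes with camera at a preset correlation of 0.01, adjusted over 224 tests of lists and comparisons. Of these, 110 were called, 59 with an estimated correlation and 101 with fry.

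For the position between ovary and testis, genes with an adjusted p under 0.05 and at least a 2-fold difference were chosen on replicates 1 and 2 of both control groups and the ends set on replicates 3 and 4, then the reverse, and both were averaged. Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d, Uty, Usp9y, Zfy1, Zfy2 and Sry were left out. Other X- and Y-linked genes, such as Uba1y, were not, and these can follow the karyotype whatever the genotype. This gave 502 and 555 genes higher in XX control and 488 and 548 higher in XY control. Groups were compared with two-sided exact permutation tests, whose smallest possible p is 0.0286, adjusted over 22 tests.

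The fit was tested on simulated data with known changes for XX DKO against XX control over 11777 genes. Of 67 genes changed 1.5-fold, 67.2% were recovered, of 67 changed 2-fold 95.5%, and of 66 changed 4-fold 98.5%, with 10 false calls among 193. On the same simulated comparison of 11777 genes, camera called a shifted list and did not call an unshifted one. A position set at 50% came out at 50.7% and 49.9%. Residuals were drawn independently for each gene, so the simulation held no correlation between genes and cannot test camera's preset correlation. Alternatives were quantile normalization, pseudocounts of 1 and 64, no filter, only the arrays of a comparison, the replicate number as a block, the mean of a gene's probe sets, eBayes without trend, a 2-fold minimum, leaving out each array in turn, other gene choices for the position, and other set tests. Leaving out XX Ctnnb1KO replicate 4 and XY DKO replicate 3 together was added after the data were seen.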

Results

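Gene expression was measured in fetal mouse gonads at embryonic day 14.5 with 31 single-colour oligonucleotide arrays, 1 per pair of gonads freed from the mesonephros. The embryos carried a Cre transgene driven by Sf1 regulatory sequence, which is active in the somatic cells of the gonad, and floxed alleles of Ctnnb1, encoding beta-catenin of the canonical WNT pathway, and of Sox9, encoding the transcription factor that drives Sertoli cell differentiation. The 8 groups were XX and XY gonads of 4 genotypes: control, with 1 floxed allele of each gene, Ctnnb1 knockout (Ctnnb1KO), Sox9 knockout (Sox9KO) and double knockout (DKO). Each group held 4 arrays except XY DKO with 3, and each array came from a separate pair of gonads. The number of arrays per group limits the precision of every comparison. The series asks what identity a gonad takes when the testis factor SOX9 and the ovary factor beta-catenin are missing separately or together.

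The targeted genes were read first. Sox9 signal was 929.1 ± 94.5 (SD, n = 4) in XY control, 23.0 ± 16.7 in XY Sox9KO (n = 4) and 26.0 ± 15.0 in XY DKO (n = 3). In XX gonads Sox9 was low already in controls, at 119.8 ± 76.6 with replicate 2 at 11.7 and the others at 119 to 174.3, with 29.1 ± 22.8 in Sox9KO and 23.5 ± 20.4 in DKO (n = 4 each). Of the other Sox9 probe sets, 1 fell in the same way in XY gonads, from 388.8 ± 39.3 to 58.4 ± 22.5 in Sox9KO and 58.0 ± 14.8 in DKO, and 1 stayed near background in every group. Group means of Ctnnb1 signal lay between 12319.2 and 13816.1 for its strongest probe set and between 3531.0 and 4060.6 for another. For the weakest of the 3, XY DKO at 1315.9 ± 65.8 (n = 3) lay below XY control at 1663.2 ± 50.9 and XY Sox9KO at 1837.6 ± 456.2, and the other 5 groups at 1641.4 to 1734.5. Whether its probe sets lie within the deleted part is not given in the sources used here, so Ctnnb1 levels check no label.

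Sex chromosome transcripts separated the XX from the XY arrays with 1 exception. Y-linked Eif2s3y averaged 3310.3 ± 236.9 in XY control and 9.9 ± 8.4 in XX control (n = 4 each). Xist, the noncoding RNA of the inactive X chromosome, averaged 8423.9 ± 889.3 in XX control and 77.1 ± 10.6 in XY control. Replicate 4 of XX Ctnnb1KO had neither: its log2 Xist value was 6.07, against 11.28 ± 3.47 over its group, and its Y-linked genes stayed at the XX level.

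**Figure D1:**
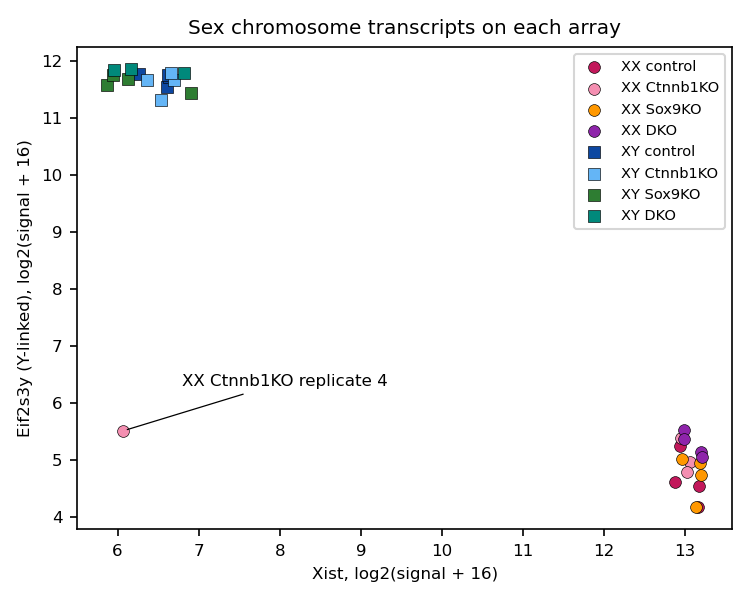
Xist against Y-linked Eif2s3y, both as log2(signal + 16), with 1 point per array coloured by group. XY arrays sit at the upper left and XX arrays at the lower right, except XX Ctnnb1KO replicate 4, which lacks both transcripts with a log2 Xist value of 6.07.

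Control testis and control ovary differed in the supporting, steroid-producing and germ cell genes. The Sertoli cell genes Dhh, a hedgehog ligand, Cst9 and Ptgds were higher in XY control than in XX control by 5.24 ± 0.17, 5.13 ± 0.14 and 5.04 ± 0.22 log2 units (SE, 4 against 4 arrays), and Hsd17b3, a testosterone-forming enzyme, by 6.44 ± 0.25. The steroidogenic enzyme genes Cyp11a1 and Cyp17a1 were higher by 7.46 ± 0.31 and 6.70 ± 0.25, and Star, the cholesterol carrier of the mitochondrion, by 3.65 ± 0.12. The ovarian genes Fst, encoding the activin antagonist follistatin, and Foxl2, a granulosa cell transcription factor, were lower by -5.26 ± 0.13 and -4.61 ± 0.15, and the homeobox genes Irx3 and Msx1 by -4.71 ± 0.17 and -4.29 ± 0.16. Stra8, Meioc and Rec8, which act at entry into meiosis, were lower by -4.21 ± 0.32, -4.73 ± 0.30 and -3.67 ± 0.16. Outside the lists, Sostdc1 and Ccl17 were higher by 5.80 ± 0.26 and 5.36 ± 0.32, and Calb1, a calcium-binding protein, was lower by -5.16 ± 0.26.

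Of 16 measured Sertoli cell and testis genes, 15 rose in XY relative to XX control and 0 fell (15 and 0 adjusted over the list alone), with a median of 3.12 and a camera adjusted p of 3.92e-20. Of 16 pregranulosa and ovary genes, 14 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -2.17 and a camera adjusted p of 5.29e-18. Among 12 canonical WNT target genes, 9 were lower and 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 3.66e-06), led by Tnfrsf19 at -3.88 ± 0.09 and Axin2 at -1.33 ± 0.12. All 7 measured fetal Leydig and steroid synthesis genes rose (7 adjusted over the list alone; camera adjusted p = 3.87e-14). Of 4 adrenal cortex genes, 3 were higher (3 adjusted over the list alone; camera adjusted p = 0.00216), among them Cyp11b1 at 4.06 ± 0.29 and Cyp21a1 at 2.0 ± 0.37. Of 8 interstitial and hedgehog target genes, 7 rose (7 adjusted over the list alone; camera adjusted p = 7.21e-09), with the hedgehog targets Hhip at 3.49 ± 0.22 and Gli1 at 3.31 ± 0.29. Of 6 peritubular myoid and smooth muscle genes, 5 rose (5 adjusted over the list alone; camera adjusted p = 0.000906), with Acta2 at 1.58 ± 0.12.

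All 18 meiosis genes were lower in XY control (18 adjusted over the list alone), with a median of -2.49 and a camera adjusted p of 7.38e-13, but an adjusted p = 0.0908 with an estimated correlation. Of 8 fetal male germ cell genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.00216, and adjusted p = 0.0768 with an estimated correlation), led by the Nodal antagonist genes Lefty2 at 4.20 ± 0.16 and Lefty1 at 3.03 ± 0.32. The 15 pan-germ cell genes moved both ways, with 5 higher and 3 lower (7 and 3 adjusted over the list alone; camera adjusted p = 0.688). Of 11 proliferation genes, 8 were higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.00406, and adjusted p = 0.156 with an estimated correlation). Of 7 immediate early and heat shock genes, which respond to handling, 4 were higher and 1 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.0052), with Egr1 at 1.71 ± 0.12 and Fos at -1.26 ± 0.25. Endothelial genes gave 5 higher of 15 (5 adjusted over the list alone; camera adjusted p = 0.117), macrophage and leukocyte genes 1 lower of 13 (0 adjusted over the list alone; camera adjusted p = 0.905), and erythroid genes 2 lower of 9 (2 adjusted over the list alone; camera adjusted p = 0.398). Of 3 mesonephric duct and tubule genes, Lhx1 was higher by 2.44 ± 0.29 and Emx2 lower by -1.26 ± 0.14 (the same counts adjusted over the list alone; camera adjusted p = 0.84), and their median, -0.38, and mean, 0.27, differed in sign. In all, limma called 4453 of 11777 genes, 2120 higher and 2333 lower in XY control, and 1046 of them differed at least 2-fold.

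**Figure D2:**
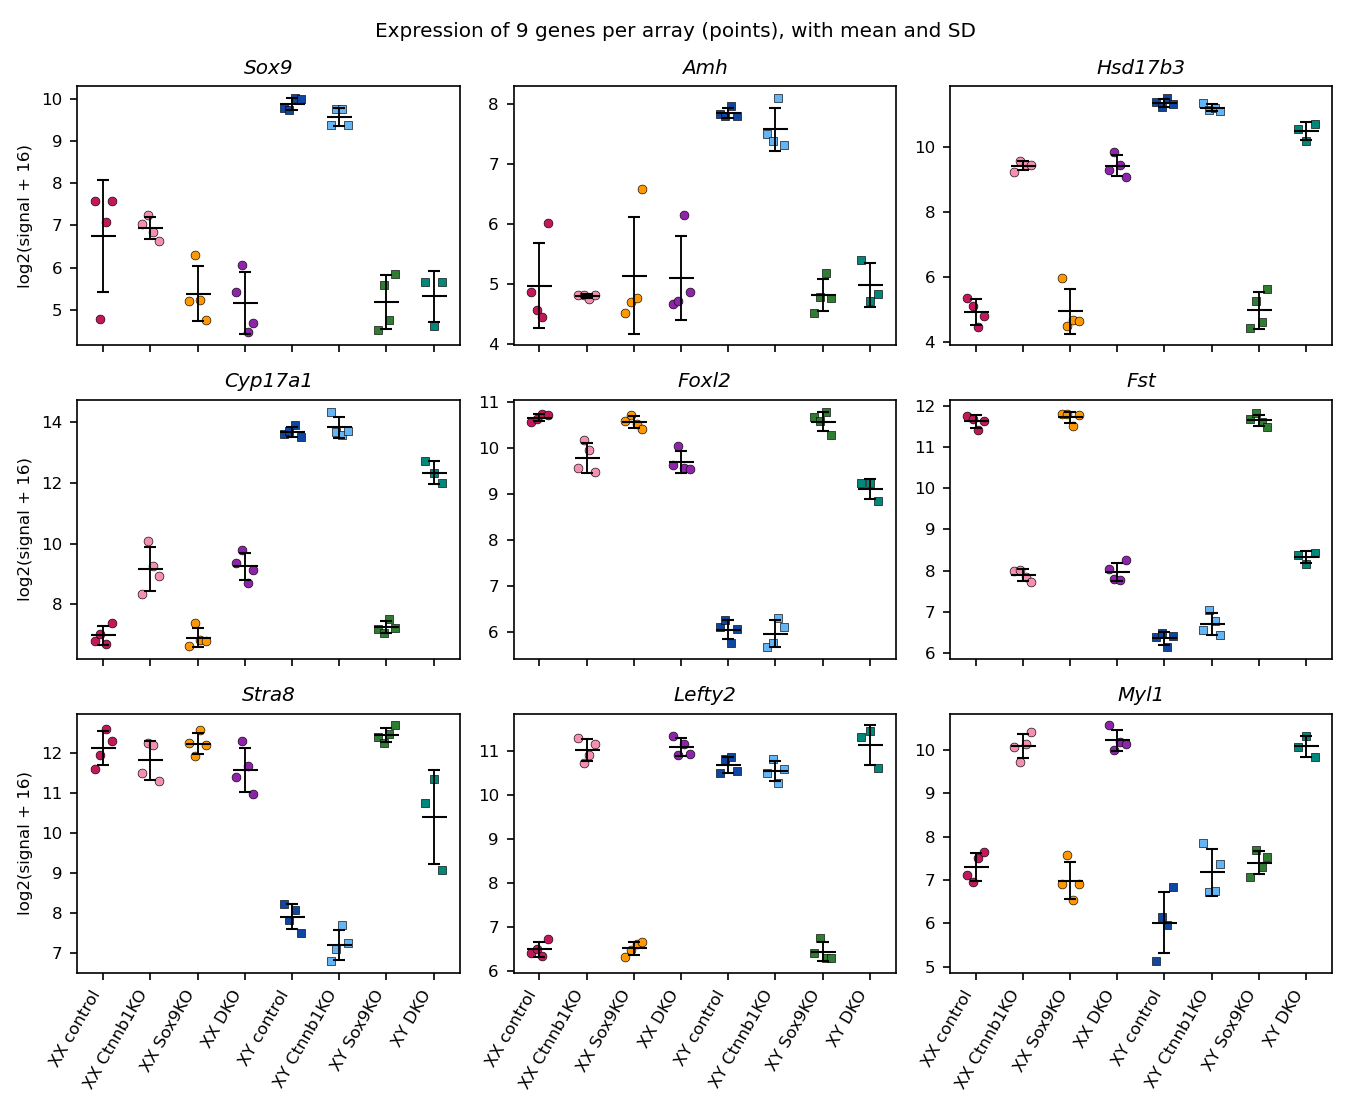
Expression as log2(signal + 16) of 9 genes in every array, grouped by sex and genotype, with circles for XX, squares for XY, and the mean with SD of each group. XX Sox9KO and XY Sox9KO lie at the XX control level for Fst and Lefty2, while Cyp17a1 in XY DKO (12.33 ± 0.37, n = 3) lies between XY Sox9KO (7.25 ± 0.19) and XY control (13.68 ± 0.16).

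The position of each array between control ovary at 0% and control testis at 100% was taken over genes that differed between the controls. Genes were chosen on 2 replicates of each control group and the ends of the scale set on the other 2, and the reverse. Within 1 pass, controls thus did not choose and scale on the same arrays. The controls that set the ends still average 0% or 100% by construction, and those that chose the genes can overshoot. Differences from a control group include this overshoot. Over genes higher in XX control, XX control lay at -4.64 ± 5.0% and XY control at 101.53 ± 2.05% (SD, n = 4 each). XX Ctnnb1KO lay at 26.19 ± 9.25% and XX DKO at 27.25 ± 7.13%, XX Sox9KO at -3.28 ± 5.90%, XY Ctnnb1KO at 96.98 ± 2.80%, XY Sox9KO at -0.74 ± 6.32% (n = 4 each) and XY DKO at 54.28 ± 3.79% (n = 3). Over genes higher in XY control the same groups lay at 23.05 ± 2.76%, 25.91 ± 3.46%, -1.67 ± 2.69%, 100.13 ± 1.16%, 1.17 ± 2.99% and 55.04 ± 2.24%. Two-sided exact permutation tests gave the smallest p these designs allow, 0.0286 (adjusted p = 0.0449 over 22 tests), for XX Ctnnb1KO, XX DKO, XY Sox9KO and XY DKO against their own control, for XY DKO against XY Sox9KO and for XY DKO against XX DKO, in both gene sets. The 22 tests include XY against XX control in both gene sets. Those groups set the scale, so their small p follows from its making and somewhat lowers the other adjusted values.

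**Figure D3:**
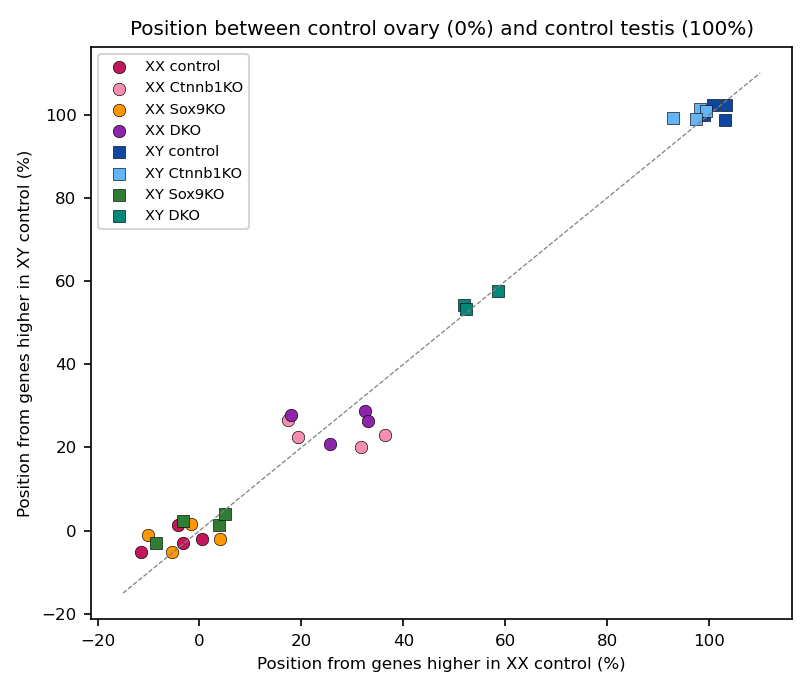
Position of each array between control ovary (0%) and control testis (100%), from genes higher in XX control on the horizontal axis and genes higher in XY control on the vertical axis, in percent. XY DKO arrays lie at 54.28% and 55.04% on average, above XX DKO at 27.25% and 25.91%.

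Loss of Ctnnb1 in XX gonads lowered ovarian genes and raised part of the testis genes. Fst was lower than in XX control by -3.73 ± 0.13, Wnt4, a signal of ovary development, by -1.20 ± 0.11, the stem cell receptor gene Lgr5 by -2.18 ± 0.16 and Foxl2 by -0.87 ± 0.15 log2 units (SE, 4 against 4 arrays), while Rspo1, an activator of WNT signalling, was higher by 0.71 ± 0.10. Foxl2 signal was 888.6 ± 206.2 in XX Ctnnb1KO against 1610 ± 88.8 in XX control and 50.9 ± 9.3 in XY control (SD, n = 4 each). Hsd17b3 rose by 4.51 ± 0.25 and Dhh by 1.39 ± 0.17, but Sox9 differed by 0.18 ± 0.44 (limma adjusted p = 0.875). Without XX control replicate 2 it differed by -0.47 (limma adjusted p = 0.54). Lefty2 rose by 4.53 ± 0.16, to 2093.4 ± 365.9 against 1647.4 ± 203.3 in XY control, and Lefty1 by 3.57 ± 0.32. Myl1, a muscle myosin light chain, Cbln1 and Fabp3 rose by 2.78 ± 0.27, 2.22 ± 0.22 and 2.04 ± 0.18, and Calb1, Thbs2 and Cntn4 fell by 4.18 ± 0.26, 2.40 ± 0.15 and 2.38 ± 0.16.

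By list, 12 of 16 pregranulosa and ovary genes fell and 1 rose in XX Ctnnb1KO (12 and 1 adjusted over the list alone; median -0.92, camera adjusted p = 1.07e-16), and 7 of 12 WNT target genes fell (8 adjusted over the list alone; camera adjusted p = 1.42e-08), with Axin2 at -0.79 ± 0.12. Of 16 Sertoli cell and testis genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone; median 0.17, camera adjusted p = 0.00229), with Vnn1 at 1.29 ± 0.15 and Aard at -1.37 ± 0.13. Of 7 Leydig and steroid synthesis genes, Star, Cyp17a1 and Cyp11a1 rose by 1.28 ± 0.12, 2.18 ± 0.25 and 2.34 ± 0.31 and Hsd3b1 fell by 1.35 ± 0.17 (the same counts adjusted over the list alone). The camera adjusted p of that list was 0.0289, and the adjusted p = 0.233 with an estimated correlation. Cyp17a1 reached a signal of 612.6 ± 329.1 there, against 13128.1 ± 1533.6 in XY control. Of 8 fetal male germ cell genes, Lefty2, Lefty1 and Nodal, at 1.54 ± 0.25, were called (3 adjusted over the list alone; camera adjusted p = 0.00011), and of 18 meiosis genes only Rec8, at -1.23 ± 0.16 (1 adjusted over the list alone; camera adjusted p = 0.0189, and adjusted p = 0.7 with an estimated correlation). Macrophage and leukocyte genes rose in 7 of 13 cases (11 adjusted over the list alone), with the complement gene C1qc at 1.06 ± 0.27 and Tyrobp at 0.81 ± 0.18. Their camera adjusted p was 2.24e-06, and the adjusted p = 0.0908 with an estimated correlation. The immediate early gene Egr1 also rose, by 1.54 ± 0.12. limma called 1192 genes, 566 higher and 626 lower, and 963 without replicate 4 of XX Ctnnb1KO.

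Loss of Sox9 in XX gonads changed no gene by limma's test after adjustment. Fst, Foxl2 and Stra8 kept signals of 3377.5 ± 304.4, 1504.2 ± 139.5 and 4896.5 ± 915.4, against 3141.7 ± 323.4, 1610 ± 88.8 and 4588 ± 1330.1 in XX control (SD, n = 4 each). Sox9 itself differed by -1.38 ± 0.44 (limma adjusted p = 0.986). Without XX control replicate 2, whose Sox9 signal was 11.7, it differed by -2.03 (limma adjusted p = 0.0363). limma called 0 genes, with 537 at an unadjusted p under 0.05. Leaving out XX control replicate 2 gave 1 called gene, Sox9, and leaving out XX Sox9KO replicate 3 also gave 1. Position differed from XX control by 1.36 and 0.51 percentage points (two-sided exact permutation p = 0.743 and 0.657). The 4 adrenal cortex genes had a median of -0.60 with 0 called (2 lower adjusted over the list alone; camera adjusted p = 0.000139), led by Mc2r at -0.84 ± 0.19 (limma adjusted p = 0.753), and the 15 pan-germ cell genes a median of -0.61 with 0 called (0 adjusted over the list alone; camera adjusted p = 1.22e-07, and adjusted p = 0.116 with an estimated correlation).

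XX gonads without both genes had less ovarian and more Lefty2 and Hsd17b3 expression than XX control, and limma called no gene between them and XX Ctnnb1KO. Against XX control, Lefty2 rose by 4.61 ± 0.16, Hsd17b3 by 4.50 ± 0.25 and Dhh by 1.68 ± 0.17, and Fst was lower by -3.65 ± 0.13, Lgr5 by -2.41 ± 0.16, Foxl2 by -0.97 ± 0.15 and Sox9 by -1.59 ± 0.44 log2 units (SE, 4 against 4 arrays). Myl1, Nupr1 and the granulocyte enzyme gene Mpo rose by 2.91 ± 0.27, 2.36 ± 0.32 and 3.63 ± 0.87, and Calb1 fell by 3.93 ± 0.26. Y-linked Eif2s3y was called higher by 0.63 ± 0.19, though near background with a signal of 23.0 ± 6.0 (SD). Pregranulosa and ovary genes gave 13 lower and 1 higher of 16 (13 and 1 adjusted over the list alone; camera adjusted p = 1.95e-14). WNT target genes gave 8 lower of 12 (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.69e-07), and Sertoli cell and testis genes 6 higher and 3 lower of 16 (7 and 4 adjusted over the list alone; camera adjusted p = 0.00918). Star, Cyp17a1 and Cyp11a1 rose by 1.33 ± 0.12, 2.27 ± 0.25 and 2.19 ± 0.31 and Hsd3b1 fell by 1.23 ± 0.17, for a list camera adjusted p of 0.0125 and an adjusted p = 0.163 with an estimated correlation. Of 13 macrophage and leukocyte genes, 9 rose (10 adjusted over the list alone; camera adjusted p = 4.78e-07, and adjusted p = 0.0767 with an estimated correlation). limma called 1519 genes, 858 higher and 661 lower. Against XX Ctnnb1KO it called 0, with 965 at an unadjusted p under 0.05, and 0 also without replicate 4 of XX Ctnnb1KO. Sox9 was lower in XX DKO by -1.77 ± 0.44 (limma adjusted p = 0.293), with signals of 6.3 to 50.9 against 82.8 to 136.5 in XX Ctnnb1KO. Position differed by 1.07 and 2.86 percentage points (two-sided exact permutation p = 0.83 and 0.286). The interaction of the Ctnnb1 and Sox9 losses in XX gonads also gave 0 calls by limma, with 471 genes at an unadjusted p under 0.05 and again 0 calls without that array.

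Loss of Ctnnb1 in XY gonads left the testis profile with 8 called genes. Those lower were Aldh1a3, a retinoic acid synthesis enzyme gene, by -1.68 ± 0.17, Atp2b3 by -1.95 ± 0.26, the transcription factor gene Pax8 by -1.61 ± 0.25, Lgr5 by -0.86 ± 0.16, Rassf10 by -0.89 ± 0.15, Trank1 by -1.01 ± 0.20 and Sacm1l by -0.47 ± 0.08, and the 1 higher was Stab2 by 0.97 ± 0.17 log2 units (SE, 4 against 4 arrays). Aldh1a3, Atp2b3, Rassf10 and Stab2 were named after their values were seen. Sox9 differed by -0.32 ± 0.44 and Cyp17a1 by 0.14 ± 0.25 (limma adjusted p = 1 for both). Another Sox9 probe set, however, read 292.0 ± 24.0 against 388.8 ± 39.3 (SD), with no overlap between arrays. None of 16 Sertoli cell and testis genes was called, with 473 of all genes at an unadjusted p under 0.05 by limma. Adjusted over the list alone, 3 of the 16 were lower, and the list had a median of -0.30 and a camera adjusted p of 1.6e-06. Of the 12 genes in the WNT target list, which leaves Lgr5 to the pregranulosa and ovary list, 0 were called (0 adjusted over the list alone), with a median of -0.13 and a camera adjusted p of 0.00238. Position differed from XY control by -4.56 and -0.66 percentage points (two-sided exact permutation p = 0.0571 and 0.543). Without XY Ctnnb1KO replicate 4, limma called 5 genes.

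Loss of Sox9 in XY gonads replaced testis expression with ovarian expression. Fst rose from 66.4 ± 8.4 to 3209.4 ± 308.4 and Foxl2 from 50.9 ± 9.3 to 1530.5 ± 221.7 in signal, against 3141.7 ± 323.4 and 1610 ± 88.8 in XX control (SD, n = 4 each). Stra8 rose from 229.8 ± 52.1 to 5677.5 ± 716.2. Cyp11a1 fell from 7901.5 ± 276.1 to 15.7 ± 15.6, Cyp17a1 from 13128.1 ± 1533.6 to 137.2 ± 21.1, Hsd17b3 from 2655.7 ± 221.3 to 17.6 ± 13.1, and Amh, encoding anti-Müllerian hormone, from 214.8 ± 13.1 to 12.5 ± 5.6. In log2 units (SE), the largest rises included Irx3 at 4.66 ± 0.17, Msx1 at 4.36 ± 0.16 and Ablim3 at 4.29 ± 0.33, and the largest falls Sostdc1 at -5.83 ± 0.26, Ccl17 at -5.62 ± 0.32, Dhh at -5.46 ± 0.17 and Gsta2 at -5.13 ± 0.20.

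In XY Sox9KO against XY control, 15 of 16 Sertoli cell and testis genes fell, Sox9 as the deleted gene among them (15 adjusted over the list alone; camera adjusted p = 4.67e-22), and 14 of 16 pregranulosa and ovary genes rose with 1 lower (14 and 1 adjusted over the list alone; camera adjusted p = 8.22e-18). WNT target genes gave 10 higher and 1 lower of 12 (10 and 1 adjusted over the list alone; camera adjusted p = 5.06e-06), with Tnfrsf19 at 4.03 ± 0.09 and Axin2 at 1.27 ± 0.12. All 7 Leydig and steroid synthesis genes fell (7 adjusted over the list alone; camera adjusted p = 1.95e-14), as did 7 of 8 interstitial and hedgehog target genes (8 adjusted over the list alone; camera adjusted p = 1.7e-09), with Hhip at -3.34 ± 0.22 and Gli1 at -3.58 ± 0.29, and 5 of 6 myoid and smooth muscle genes (5 adjusted over the list alone; camera adjusted p = 0.000906). All 18 meiosis genes rose (18 adjusted over the list alone; camera adjusted p = 2.8e-11, and adjusted p = 0.116 with an estimated correlation). The heat shock gene Hspa1b and Egr1 were lower by -2.66 ± 0.19 and -1.59 ± 0.12. limma called 4559 genes, 2677 higher and 1882 lower.

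Set directly against XX control, the called differences of at least 2-fold in XY Sox9KO gonads were all in sex-linked genes. Y-linked Eif2s3y, Uba1y and Kdm5d were higher by 6.97 ± 0.19, 6.93 ± 0.25 and 5.58 ± 0.23, and the X-linked genes Xist and Kdm6a lower by -6.83 ± 0.80 and -0.70 ± 0.11 (SE, 4 against 4 arrays). Autosomal Alg9 was higher by 0.66 ± 0.10. No member of the 16 cell type, pathway and handling lists was called. Adjusted over the list alone, 2 Sertoli cell and testis genes were lower and 1 gene each of the pregranulosa and ovary, interstitial and hedgehog target, myoid and smooth muscle, and endothelial lists was higher. The Sox9 difference was -1.57 ± 0.44 (limma adjusted p = 0.0634). Without XX control replicate 2 it was -2.23 and called (limma adjusted p = 0.00114). The Wnt4 difference was 0.45 ± 0.11 (limma adjusted p = 0.0545). limma called 74 genes, 52 higher and 22 lower, of which 6 differed at least 2-fold. At an unadjusted p under 0.05 there were 2136. Of the 74, 5 are Y-linked, 15 X-linked and 54 autosomal. The autosomal ones differ by at most 0.66. This count depended on single arrays: it was 27, 13, 8 and 228 without XX control replicates 1 to 4 in turn, and 162, 215, 36 and 9 without XY Sox9KO replicates 1 to 4. Position differed by 3.91 and 3.35 percentage points (two-sided exact permutation p = 0.371 and 0.2).

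XY gonads without both genes carried ovarian and testis transcripts together. Against XY control, the ovarian genes Foxl2, Rspo1 and Fst rose by 3.06 ± 0.17, 2.55 ± 0.11 and 1.97 ± 0.14 log2 units, and the Sertoli cell genes Cst9, Tesc and Col9a3 were lower by -3.28 ± 0.15, -3.63 ± 0.17 and -4.24 ± 0.24 (SE, 3 against 4 arrays). Cyp17a1 signal was 5258.5 ± 1343.2, Cyp11a1 2665.1 ± 278.8 and Hsd17b3 1442.3 ± 267.7 (SD, n = 3), while Amh was 16.3 ± 8.6. Stra8 rose by 2.49 ± 0.35, with a signal of 1624 ± 1045.3, replicate 4 at 530.1 and replicates 2 and 3 at 1729.1 and 2612.8. Lefty2 was 2311.1 ± 664.1, against 1647.4 ± 203.3 in XY control and 71.7 ± 14.1 in XY Sox9KO. It was as high in XX DKO, at 2201.5 ± 316.5, so its level is not particular to testis. Myl1, Tnnc1 and Tnnt2, genes of the contractile apparatus of striated muscle, rose by 4.06 ± 0.29, 2.66 ± 0.30 and 2.25 ± 0.29, and Nupr1 and the erythroid gene Hemgn by 2.54 ± 0.35 and 2.22 ± 0.58. Nts and Cited1 fell by 3.64 ± 0.31 and 3.56 ± 0.44.

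Of 16 Sertoli cell and testis genes, 14 were lower in XY DKO than in XY control (14 adjusted over the list alone; median -2.15, camera adjusted p = 7.88e-25), and of 16 pregranulosa and ovary genes 12 were higher and 1 lower (13 and 1 adjusted over the list alone; median 1.02, camera adjusted p = 7.97e-14). WNT target genes gave 2 higher and 1 lower of 12 (2 and 1 adjusted over the list alone; camera adjusted p = 0.179), with Tnfrsf19 at 1.48 ± 0.10 and Nkd2 at -0.51 ± 0.15. All 7 Leydig and steroid synthesis genes were lower (7 adjusted over the list alone; median -1.21, camera adjusted p = 6.12e-11), and 5 of 8 interstitial and hedgehog target genes (5 adjusted over the list alone; camera adjusted p = 5.06e-06), with Hhip at -3.11 ± 0.24. Meiosis genes rose in 10 of 18 cases (12 adjusted over the list alone; camera adjusted p = 2.63e-07, and adjusted p = 0.242 with an estimated correlation). Macrophage and leukocyte genes rose in 8 of 13 (10 adjusted over the list alone; camera adjusted p = 7.04e-06, and adjusted p = 0.111 with an estimated correlation), with C1qb at 1.18 ± 0.16. limma called 2029 genes, 1133 higher and 896 lower. Replicate 3 of XY DKO had the lowest median signal of all arrays, 120.6, and the highest actin 3' to 5' ratio, 1.212, and without it 1389 genes were called. Replicate 4 had the next highest actin ratio, 1.14, and the lowest mean correlation with its own group, 0.9639. Without it 2014 were called. As a group XY DKO had the highest mean actin and Gapdh ratios, 1.11 and 2.96, and the lowest mean correlation, 0.968. Its replicate 2, however, had an actin ratio of 0.977. XX DKO had the lowest mean actin ratio of all groups, 0.986, a mean correlation of 0.978 and the next highest Gapdh ratio, 2.87. Not all these measures moved with double loss in both sexes, but within XY DKO they cannot be told apart from genotype.

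Ctnnb1 loss on top of Sox9 loss moved XY gonads back toward the testis profile. Compared with XY Sox9KO, XY DKO had more Cyp11a1, Hsd17b3 and Cyp17a1, by 6.51 ± 0.33, 5.51 ± 0.27 and 5.08 ± 0.27 log2 units, more Lefty2, by 4.70 ± 0.17, and more Dhh, by 3.13 ± 0.18 (SE, 3 against 4 arrays). Cnmd, Gsta2, Cbln1 and Inhba, an activin subunit gene, were higher by 4.30 ± 0.33, 4.02 ± 0.21, 3.96 ± 0.24 and 3.29 ± 0.16. Calb1, Ablim3, Fst, Lgr5 and Msx1 were lower by -4.00 ± 0.28, -3.41 ± 0.36, -3.32 ± 0.14, -3.0 ± 0.17 and -2.93 ± 0.17, and Foxl2 by -1.47 ± 0.17. Sox9 did not separate the groups, at 0.14 ± 0.47 (limma adjusted p = 0.871).

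In this comparison 12 of 16 pregranulosa and ovary genes fell and 2 rose (13 and 2 adjusted over the list alone; camera adjusted p = 5.71e-14), and 8 of 12 WNT target genes fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 1.79e-07). Of 16 Sertoli cell and testis genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone; median 0.58, camera adjusted p = 8.08e-06). Leydig and steroid synthesis genes rose in 6 of 7 cases (7 adjusted over the list alone; camera adjusted p = 7.38e-13), and interstitial and hedgehog target genes in 6 of 8 (6 adjusted over the list alone; camera adjusted p = 8.05e-06), with Gli1 at 2.46 ± 0.31. Meiosis genes fell in 11 of 18 cases (14 adjusted over the list alone; camera adjusted p = 4.34e-07, and adjusted p = 0.25 with an estimated correlation), and 4 of 8 fetal male germ cell genes rose (4 adjusted over the list alone; camera adjusted p = 0.000612, and adjusted p = 0.051 with an estimated correlation). Macrophage and leukocyte genes rose in 10 of 13 (12 adjusted over the list alone; camera adjusted p = 3.43e-06, and adjusted p = 0.0959 with an estimated correlation). Immediate early and heat shock genes rose in 5 of 7 (5 adjusted over the list alone; camera adjusted p = 0.00023), with Egr1 at 1.68 ± 0.13. limma called 2572 genes, 1303 higher and 1269 lower, and 2199 without the XX Ctnnb1KO and XY DKO arrays named above. In a fit of only the arrays of these groups it called 1705.

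**Figure D4:**
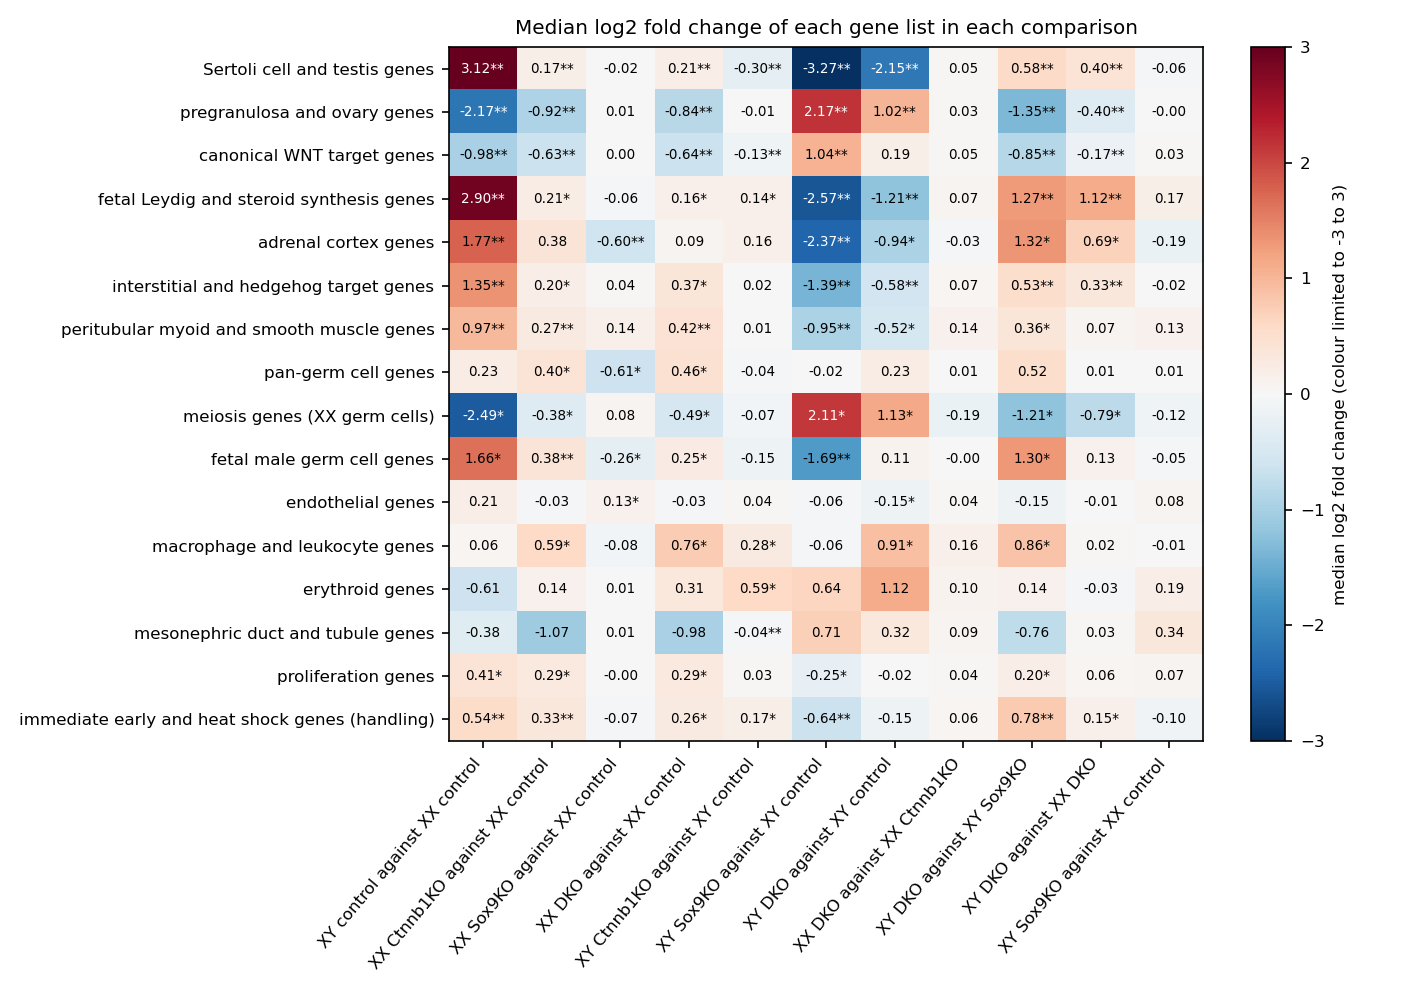
Median log2 fold change of each gene list (vertical) in each comparison (horizontal), with colour limited to -3 to 3; 1 asterisk marks a camera adjusted p under 0.05 and 2 asterisks a list that also passes with an estimated correlation. Sertoli cell and testis genes have medians of 3.12 in XY against XX control and -3.27 in XY Sox9KO against XY control.

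XY and XX gonads that lacked both genes still differed in steroid synthesis genes. Cyp11a1, Cyp17a1 and Hsd3b1 were higher in XY DKO than in XX DKO by 3.71 ± 0.33, 3.08 ± 0.27 and 2.83 ± 0.19 log2 units, and Gsta2 and Hao2 by 2.30 ± 0.21 and 2.28 ± 0.19 (SE, 3 against 4 arrays). Dhh and Cyp26b1, a retinoic acid degrading enzyme gene, were higher by 1.24 ± 0.18 and 1.33 ± 0.22, and Msx1, Irx3, Kitl and Foxl2 lower by -1.26 ± 0.17, -1.24 ± 0.18, -0.76 ± 0.12 and -0.58 ± 0.17. Rhox9 and Meioc were lower by -2.34 ± 0.32 and -1.39 ± 0.33. All 7 Leydig and steroid synthesis genes were higher (7 adjusted over the list alone; camera adjusted p = 6.47e-21), as were 6 of 16 Sertoli cell and testis genes (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000906). Of 16 pregranulosa and ovary genes, 5 were lower (8 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.000122). limma called 615 genes, 406 higher and 209 lower. The count was 391 without XX DKO replicate 2, 349 without XX DKO replicate 3, 366 without XY DKO replicate 4, and 179 in a fit of only these groups' arrays.

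Interaction terms tested whether the effects themselves differed. The effect of double loss differed between the sexes in 1758 genes by limma, with Fst at 5.62 ± 0.19 and Foxl2 at 4.03 ± 0.23 more positive in XY and Hsd17b3 at -5.39 ± 0.37 and Cst9 at -4.59 ± 0.21 more negative in XY (SE). Within XY gonads, limma called a departure of the double loss from the sum of the single losses in 1148 genes, with Cyp11a1 at 6.44 ± 0.45, Lefty2 at 4.83 ± 0.23, Calb1 at -4.31 ± 0.38 and Fst at -3.67 ± 0.19. Of the interactions added after the data were seen, the effect of Ctnnb1 loss differed between the sexes in 494 genes (429 without XX Ctnnb1KO replicate 4), with Lefty2 at -4.66 ± 0.22 and Fst at 4.08 ± 0.18, and that of Sox9 loss in 2749, with Fst at 5.19 ± 0.18 and Foxl2 at 4.63 ± 0.22.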

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

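Of the tests in this part, the comparison of Y-linked genes in XX Ctnnb1KO replicate 4, and the interactions of sex with Ctnnb1 loss and of sex with Sox9 loss, were chosen after the results were seen.

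Replicate 4 of XX Ctnnb1KO stood apart in Xist, with a log2 value of 6.07, while the other arrays of its group carried XX levels. Its mean over Eif2s3y and Kdm5d was 5.16, against at most 5.27 in XX arrays of other groups and at least 10.64 in XY arrays, which argues against an XY gonad under an XX label. Over 394 X-linked genes the array lay at a median of -0.126 (SE 0.023) relative to the other 3 arrays and to autosomal genes, which argues against Xist silence with both X chromosomes active. The mean of 6 genes that escape X inactivation was 10.95, lower than in the other 3 arrays (11.27 to 11.30) by -0.33, with 5 of the 6 genes below all 3 arrays and Utp14a at a difference of 0. One X chromosome in place of a pair may therefore underlie this array, a hypothesis that only a karyotype could settle.

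Groups of 4 arrays were screened for a single array apart, which leaves XY DKO, with 3 arrays, untested. A single array lay apart from its group in 18 of 266 groups of values, where chance alone gives about 13.3. In XY control these were replicate 1 in the WNT target score, at -0.617, replicate 2 in the meiosis score, at -1.784, and in Xist, at 6.27, and replicate 3 in the adrenal cortex score, at 1.495, and the myoid and smooth muscle score, at 0.615. In XX control replicate 2 lay apart in the endothelial score, at 0, and replicate 1 in the actin 3' to 5' ratio, at 1.078, and in its mean correlation with its own group, at 0.9669. Log2 Uty was 4.90 in XX Ctnnb1KO replicate 4 and 4.92 in XX Sox9KO replicate 2. Log2 Amh was 4.75 in XX Ctnnb1KO replicate 3, 6.58 in XX Sox9KO replicate 4 and 6.14 in XX DKO replicate 3. Log2 Fst was 11.52 in XX Sox9KO replicate 3 and log2 Hsd17b3 5.98 in XX Sox9KO replicate 1. XY Ctnnb1KO replicate 1 was highest of its group in Cyp17a1, at 14.34, and Cyp11a1, at 13.34.

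Effects differed between groups by limma's interaction test in 1758 genes for double loss between the sexes, 494 for Ctnnb1 loss between the sexes, 2749 for Sox9 loss between the sexes and 1148 for the combined losses in XY gonads. Among probe sets without exactly 1 gene name, which no comparison used, 326 of 3933 differed at least 2-fold between XY and XX control, 173 higher and 153 lower, or 8.29% against 8.88% of named genes.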

How the results depend on the processing

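Of the tests in this part, leaving out the arrays XX Ctnnb1KO replicate 4 and XY DKO replicate 3 together, and every setting of the interactions of sex with Ctnnb1 loss and with Sox9 loss, were chosen after the results were seen. Alternative values were taken of counts of called genes, positions and counts of called list tests. Of these 485, 444 stayed within 1.5 times a count or within 1 SD of a position. Single list tests are not among them, and 51 of the 110 called lost their call with an estimated correlation. Quantile normalization, both pseudocounts, the replicate block, the mean of probe sets and leaving out 1 array reversed no called direction of a named gene, and no scaling flipped the direction of a comparison.

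A 2-fold minimum left 1046 genes for XY against XX control, 250 for XX Ctnnb1KO, 269 for XX DKO, 4 for XY Ctnnb1KO, 1011 for XY Sox9KO, 458 for XY DKO, 563 for XY DKO against XY Sox9KO, 107 for XY DKO against XX DKO, 6 for XY Sox9KO against XX control, 613 for sex by double loss, 462 for Ctnnb1 by Sox9 in XY, 200 for sex by Ctnnb1 loss and 1005 for sex by Sox9 loss, fewer by construction. With only the arrays of the comparison, XY DKO against XY Sox9KO gave 1705, XY DKO against XX DKO 179 and XY Sox9KO against XX control 7, where fewer arrays estimate the spread. XY Sox9KO against XX control also gave 38 with eBayes without trend and 30 with no filter, against 74; the cause was not tested. Leaving out 1 array gave 8 to 228 genes for it, 349 to 660 for XY DKO against XX DKO, 5 to 10 for XY Ctnnb1KO and 0 to 1 for XX Sox9KO. Without both doubted arrays XX Ctnnb1KO gave 969 genes, XY DKO 1371 and XY DKO against XX DKO 454.

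Of positions, XX Ctnnb1KO over genes higher in XY control moved to 20.2% with a pseudocount of 64. XY DKO moved to 49.66% over genes higher in XX control with quantile normalization, and over genes higher in XY control to 57.66% with quantile normalization, 52.64% with the mean of probe sets, 57.51% with no 2-fold minimum and 52.19% with a pseudocount of 64. XY Sox9KO over genes higher in XY control moved to 4.51% with no 2-fold minimum and 5.09% with quantile normalization. The cause was not tested. Camera called 59 of 224 list tests with an estimated correlation, against 110. Of 1201 named values, 25 lost and 10 gained a call with the mean of probe sets. Of 12209 named values with 1 array left out, 379 lost and 61 gained a call.

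Replicate numbers did not pair the arrays: arrays with the same number had a mean correlation of -0.006 against 0.002 for other numbers, and 0 of 28 pairs of groups had every same-number correlation above 0.1. With the replicate block, counts were 4426 for XY against XX control, 1178 for XX Ctnnb1KO, 4516 for XY Sox9KO and 1896 for XY DKO. Genes near background have a wide spread and a compressed fold change, which limits what low signals can show.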

Other observations

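In this part the tests of Sox9 level, of the share of Sox9 kept, of adrenal enzymes, XX steroid genes and smooth muscle genes were chosen after the results were seen, as were the further gene sets and the final reading of the striated muscle test and the rule for reading the XX steroid test. The exchange of residuals for the interactions was chosen after the counts of the splits were seen.

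The 3 genes of duct and tubule development did not move together. In XX Ctnnb1KO, Lhx1 was higher than in XX control by 2.15 ± 0.29 and Emx2 and Pax8 lower by -1.07 ± 0.14 and -1.70 ± 0.25 log2 units (SE, 4 against 4 arrays; all called by limma). In XX DKO the values were 2.23 ± 0.29, -0.98 ± 0.14 and -1.54 ± 0.25. Between XY DKO and XY Sox9KO they were 2.56 ± 0.32, -0.76 ± 0.15 and -2.17 ± 0.27. In XY Ctnnb1KO Pax8 was lower by -1.61 ± 0.25, but Lhx1 at 0.11 ± 0.29 and Emx2 at -0.04 ± 0.14 were not called. Camera adjusted p-values of the list were 0.162 in XX Ctnnb1KO, 0.245 in XX DKO, 0.464 in XY DKO against XY Sox9KO and 0.00529 in XY Ctnnb1KO.

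Of 15 pan-germ cell genes, 5 rose in XX Ctnnb1KO and 4 in XX DKO, and none fell (5 and 4 adjusted over the list alone). Nanog, Pou5f1 and Dppa3 rose in XX Ctnnb1KO by 1.62 ± 0.45, 1.23 ± 0.35 and 0.98 ± 0.30, and Dppa3, Tcl1 and Pou5f1 in XX DKO by 1.16 ± 0.30, 1.34 ± 0.35 and 1.33 ± 0.35 log2 units. The list medians were 0.40 and 0.46, with camera adjusted p-values of 0.00484 and 0.0256, and adjusted p = 0.479 and adjusted p = 0.606 with an estimated correlation, so the list as a whole is not called in that case.

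Steroid synthesis genes were far higher in XY DKO than in XY Sox9KO. Deletion that left Sox9 in proportion to these genes is argued against, since Sox9 lay at -4.56 (SE 0.47) relative to XY control and the list's median at -1.21 (SE 0.17), and only a remainder too small for the difference from XY Sox9KO, 0.14 (SE 0.47), to resolve stays open. The adrenal enzymes Cyp21a1 and Cyp11b1 were higher by 1.99 (SE 0.28) on average, which a larger share of adrenal cortex tissue would give, but both were also high in XY control, at log2 values of 8.38 and 8.79, so a return of fetal Leydig cells would give it too and both may apply. In XX gonads, where XX DKO against XX Sox9KO shares no array with this pattern, the list's median difference was 0.23 (SE 0.72), with Star, Cyp11a1 and Cyp17a1 higher by 1.39, 2.83 and 2.34 and Hsd3b1 lower by -1.51. That value lies below the bound of 0.25 first written as excluding a rise without Sox9 in XX gonads. The bound was set aside after the value was seen, because it allowed for no error and the members go both ways. The test therefore leaves the list as a whole open, but its genes are split. Star, Cyp11a1 and Cyp17a1 were called higher (limma adjusted p = 4.14e-10, 3.79e-08 and 3.79e-08) and Hsd3b1 lower (limma adjusted p = 9.78e-08). Scarb1, Fdx1 and Nr5a1 were not called.

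Myl1, Tnnc1 and Tnnt2 were among the largest rises in XY DKO. A larger share of smooth muscle or peritubular cells is argued against by that list. Of its 6 genes, limma called 4 lower and 0 higher, with a median of -0.52 (SE 0.19, from the spread between genes). Striated muscle in the dissected tissue was tested with all 25 other striated muscle genes. Their median of 0.54 (SE 0.22) plus 2 SE, 0.98, met the bound of 1 set for excluding it. Of the 25, however, 10 lie under the expression filter, where a small rise is compressed. A large rise would lift such genes off the floor, and these 10 ran only from -0.89 (Nppa) to 0.87 (Acta1). Over the 15 above the filter, which a rise in XY DKO helps to pass, the median was 0.86 (SE 0.31), with 5 called higher and 2, Tnni3 and Casq2, called lower, and over the 9 above the median of their array in XY control, a choice without XY DKO, it was 0.54 (SE 0.42), or 1.37 with 2 SE. Myl1 itself was not raised in XY DKO alone. Its signal was 1088 ± 212.9 in XX Ctnnb1KO, 1189.9 ± 214.6 in XX DKO (SD, n = 4 each) and 1079.6 ± 186.9 in XY DKO (n = 3). In XX control it was 145.1 ± 35.1 and in XY control 54.7 ± 33. The other striated muscle genes go both ways in XY DKO, so striated muscle stays open for Myl1, Tnnc1 and Tnnt2 as a set.

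Other splits of the same arrays tested whether chance could give as many called genes. Of 35 splits, only the real one, 1, reached its count in XY against XX control (4453, highest other 395), XX Ctnnb1KO (1192, 20) and XX DKO (1519, 88). The same held for XY Ctnnb1KO (8, 1), XY Sox9KO (4559, 4) and XY DKO (2029, 877). It also held for XY DKO against XY Sox9KO (2572, 2037), XY DKO against XX DKO (615, 151) and XY Sox9KO against XX control (74, 14). A share of 1 in 35 is the smallest possible and is not adjusted over comparisons. It therefore argues against chance without excluding it. Where XY arrays are set against XX arrays, sex-linked genes can also part the real groups by karyotype alone. Of the 74 genes of XY Sox9KO against XX control, 5 are Y-linked and 15 X-linked, together more than the 14 of the highest other split. The share for that comparison therefore does not test chance for its 54 autosomal genes. The count for XY Sox9KO against XX control fell to 8 without XX control replicate 3, below the 14 of its highest other split. For XX Sox9KO and XX DKO against XX Ctnnb1KO all 35 splits reached the real count of 0, with highest others of 8 and 21.

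For interactions, splits exchange arrays between genotypes of the same sex, so the arrays have a structure and effects of the single losses can enter the counts of other splits. Of 100 such splits, 1 reached the real count for sex by double loss (1758, highest other 1433) and for sex by Ctnnb1 loss (494, 48), 2 for sex by Sox9 loss (2749, 2769), 5 for Ctnnb1 by Sox9 in XY (1148, 2838) and all 100 for Ctnnb1 by Sox9 in XX (0, 150). A further test fitted the main effects first and exchanged only residuals. Only the real arrangement, 1 of 100, then reached the count for sex by double loss (highest other 362) and sex by Ctnnb1 loss (1). The same held for sex by Sox9 loss (1377) and Ctnnb1 by Sox9 in XY (363). This is the smallest share 100 arrangements can give, and it argues against chance for the interactions with sex. For Ctnnb1 by Sox9 in XY the splits, at 5 of 100, met the bound of 5% set beforehand for leaving chance open. Only the exchange of residuals, chosen after those counts were seen, argues against chance there. For Ctnnb1 by Sox9 in XX all 100 reached the real count of 0 (highest other 337).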
